A study of Mus musculus with 18 samples.

How the data were processed

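Source and upstream processing. The deposited values are FPKM computed by the authors, in a table of 23899 genes for 18 libraries and in separate tables for 15 libraries. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.22.0.422, quantified with Salmon 0.13.0 on mm10 and normalised with DESeq2 1.22.1 in R 3.5.3. Per the sample protocols, RNA was extracted with TRIzol, poly(A) RNA was isolated and libraries were made with NEBNext Ultra II Directional kits. The files held FPKM and not counts, so the fallback test written in the design (limma-trend) was used, and edgeR, DESeq2 and other tests on counts were not used here. Which guide targets which domain, what mock received and whether replicates are separate cultures are not given in the sources used here. Raw reads were not analysed here.

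Checks of the values. The 15 separate tables differ from the series table by at most 3.3e-06 FPKM, and 25 gene names per separate table are date-like, so names were taken from the series table. Depth was estimated from the steps of FPKM times transcript length in 1473 genes with a single transcript of at least 2000 bases: in each library 99.7 to 100.0% of low values lie within 10% of a whole number of reads, where an even spread gives 50.0%. Estimated depths are 20.7 to 182.2 M reads (median 32.05), and 1 FPKM of a 2 kb transcript stands for 41 to 364 reads. Mock replicate 1 is deepest at 182.2 M reads, then e21.1 replicate 3 at 74.9 and e12.3 replicate 3 at 66.8 M reads. Gene symbols were placed with GENCODE vM21 (GRCm38), which holds 98.92% of them.

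Tests. Values were transformed as log2(FPKM + 1), and 11550 genes with a mean of at least 1 FPKM over the 18 libraries were tested with limma-trend (limma 3.58.1, R 4.3.3) in a model of group means without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes count as called. The comparison of the 4 guides together weights each guide equally. Guides were paired by the shared start of their names. Jmjd1c was also tested by an exact two-sided permutation of its log2(FPKM + 1) values. Agreement between guides was measured by Pearson and Spearman correlation across genes beside 50 simulated draws of unchanged groups with shared controls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.

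Gene lists. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined. The 29 lists, taken from general knowledge of these pathways, hold MLL-fusion targets, stem and progenitor, monocyte and macrophage, primary granule, mature neutrophil, interleukin-3 and STAT5, RAS-MAPK, MYC and ribosome biogenesis, S-phase, G2/M, p53, BCL2-family and caspase, glycolysis, oxidative phosphorylation, cholesterol, fatty acid, ATF4, interferon, NF-kB, antigen presentation, H3K9 methylation, mast cell, erythroid, megakaryocyte, lymphoid, dendritic, stromal, mitochondrially encoded and ribosomal protein genes. They were tested with limma camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted over the 25 lists, and again with an estimated correlation and with fry, which called 15 lists for the 4 guides together (17 in its mixed form). Too few members were tested for the erythroid (2), megakaryocyte (2), lymphoid (2) and dendritic (4) lists.

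Named genes. For the 4 guides together, the 10 called genes with the largest change in each direction are named, among genes with a mean of at least 5 FPKM and all 12 guide libraries on the same side of the Renilla mean; for single guides, the 5 in each direction without overlap of the groups. Gene models without a symbol of their own were skipped, and pseudogenes such as Rpl30-ps9 (log2 fold change -2.38) did not meet the rule of 12 libraries. For each list up to 4 tested members with the smallest p were eligible. Jmjd1c and 9 genes chosen beforehand are always given. The genes named beside Mpo, Csf2rb and Hoxa9 in the comparisons of guide pairs, and those behind small counts, were picked after the values were seen.

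Alternatives. Run as planned: pseudocount 0.1, no filter, a stricter filter (5 FPKM in 3 libraries), only the groups of a comparison in the model, the replicate number as a block, each library or guide left out, Renilla and mock together as control, estimated correlation and fry for the lists, and agreement among genes of at least 5 FPKM. Added after the data were seen: upper-quartile and median-of-ratios scaling of FPKM, array quality weights, the 2 or 4 libraries that stand apart left out, mock as control, protein-coding genes only, means per guide, and separate controls for agreement. Upper-quartile factors are 0.985 to 1.055; median-of-ratios factors are all 1.006, which moves nothing and tests nothing.

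Test on simulated data. With changes planted in 200 genes of simulated data, the comparison of the 4 guides recovered 53.7, 88.1 and 98.5% of changes of 0.5, 1 and 2 log2 units, and 3% of its calls were false. Single guides recovered 34.3 to 38.8, 77.6 to 83.6 and 98.5%, with 2.7 to 5.8% false calls, and the pair difference 70.1, 92.5 and 98.5%, with 1.7% false calls. In the data simulated with the same changes in all 4 guides, the 4 comparisons without a call in the real data gave 0 calls. No difference was planted between the sides of these comparisons. Noise was drawn independently for each gene and library, and changes were planted only in better expressed genes. The real libraries deviate together (correlation up to 0.76 between libraries of different groups). The rates above therefore describe the simulated data and need not hold for the real data.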

Results

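Poly(A) RNA was sequenced from cultured mouse leukaemia cells that carry Cas9 and MLL-AF9, the fusion oncoprotein of KMT2A and MLLT3, with guide RNAs against Jmjd1c. Jmjd1c encodes a nuclear jumonji protein of the H3K9 demethylase family, and the guides were directed against its jumonji and zinc finger domains. The cells came from a primary mouse leukaemia and grew with mouse interleukin-3, a cytokine that sustains myeloid progenitors. The 18 libraries form 6 groups of 3: the guides e12.3, e12.4, e20.1 and e21.1, a control guide against Renilla luciferase, and mock. The labels give neither the domain that each guide targets, nor what mock received, nor whether the 3 libraries of a group are separate cultures, so p-values measure only the spread between these libraries. Estimated depth was 20.7 to 182.2 M reads (median 32.05), and 11550 genes with a mean of at least 1 FPKM were tested.

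In e12.3 replicate 3 and e21.1 replicate 3, Mpo (the granule enzyme myeloperoxidase) stood at 1020 and 664 FPKM and Itgam (the integrin CD11b) at 47.4 and 55.7 FPKM. ATF4 stress genes stood higher there than in the other libraries of their groups, and cholesterol synthesis, S-phase and monocyte genes lower. On principal component 2 (21.9% of variance) these libraries scored -41.1 and -49.9, and all others above 0. Component 1 (26.2%) parted the other 10 Jmjd1c guide libraries (6.6 to 19.2) from the 6 control libraries (-35 to -14.3). On component 1, e12.3 replicate 3 scored -21.6, within the range of the controls. The score of e21.1 replicate 3 was -3.2, between the 2 ranges. Renilla replicate 1 and e20.1 replicate 2 scored -34.3 and -33.6 on component 3 (13.6%). Results without replicate 3 of e12.3 and of e21.1 are given beside the gene lists that these libraries move with.

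**Figure D1:**
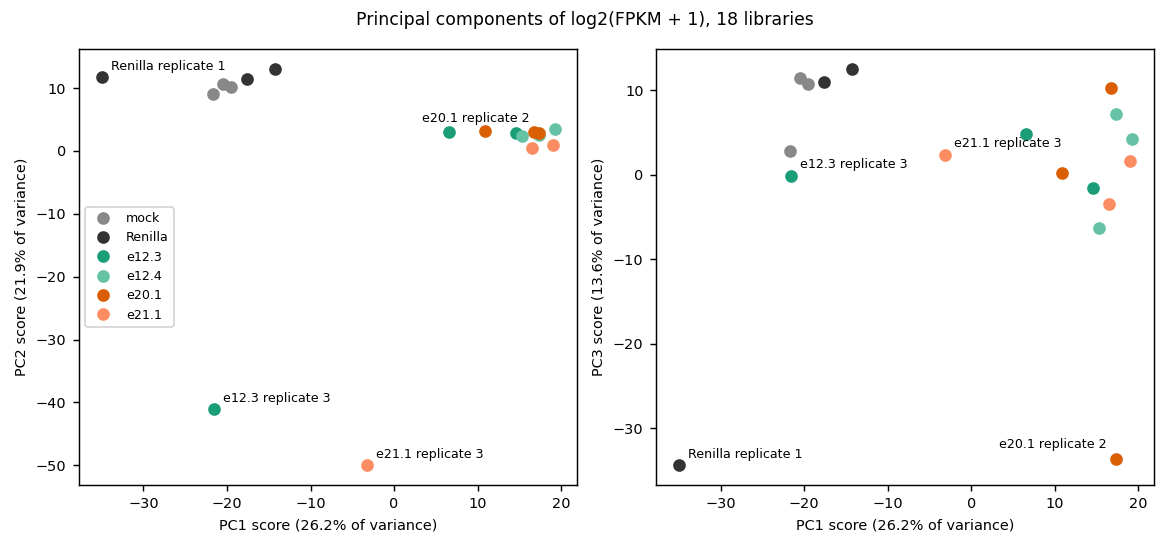
Principal component scores of log2(FPKM + 1) for the 18 libraries (1 dot each, coloured by group), component 1 against component 2 (left) and component 3 (right). Replicate 3 of e12.3 and of e21.1 sit at -41.1 and -49.9 on component 2 and at -21.6 and -3.2 on component 1. Renilla replicate 1 and e20.1 replicate 2 sit at -34.3 and -33.6 on component 3.

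Jmjd1c itself (ENSMUSG00000037876.17, GRCm38/mm10 chromosome 10, 67096125-67256326, plus strand) was measured at 64.1 ± 9.24 FPKM over the 12 guide libraries and 78.3 ± 12 FPKM over the 3 Renilla libraries, 18.1% less. Jmjd1c was at 64.2, 85.4 and 85.4 FPKM in Renilla replicates 1 to 3 and at 71.8, 77.1 and 74.5 in mock. Jmjd1c stood at 66.6, 58.8 and 56.2 FPKM with e12.3, 59.7, 74.4 and 70.9 with e12.4, 63.4, 42.2 and 73.6 with e20.1, and 62.4, 73.2 and 68.0 with e21.1. All 12 guide libraries lie below the Renilla mean. The log2 fold change of Jmjd1c was -0.29 (SE 0.13, limma adjusted p = 0.19), and the exact permutation test over 455 arrangements gave p = 0.0747. Per guide, Jmjd1c means were 60.5 ± 5.4 (e12.3, exact p = 0.2), 68.3 ± 7.69 (e12.4, exact p = 0.3), 59.8 ± 16 (e20.1, exact p = 0.2) and 67.9 ± 5.4 FPKM (e21.1, exact p = 0.3), where 20 arrangements allow no p under 0.1. Transcript level does not measure editing of the gene, which these data do not hold.

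With the 4 Jmjd1c guides together, Ctss, the lysosomal protease cathepsin S of monocytes, rose from 4.04 ± 0.808 FPKM in Renilla (n = 3) to 51.3 ± 13.9 FPKM (n = 12), a log2 fold change of 3.34 (SE 0.16, limma adjusted p = 1.9e-08). Wfdc17, a secreted regulator of macrophage activation, rose from 25.3 ± 1.34 to 271 ± 87 FPKM, and Lsp1, an actin-binding protein of leukocytes, from 4.70 ± 0.638 to 46.1 ± 12 FPKM. Ccl3, the chemokine MIP-1 alpha, rose from 9.34 ± 3.12 to 68.8 ± 17.5 FPKM, and Serpina3g, a protease inhibitor, from 8.19 ± 0.973 to 59.6 ± 22.1 FPKM. The immunoglobulin-like receptors Lilra6 (3.55 to 32.6 ± 7.67 FPKM), Lilr4b (10.3 ± 4.96 to 68.0 ± 23.4), Lilrb4a (22.8 ± 8.34 to 140 ± 41.6) and Pira2 (2.82 ± 1.29 to 21.6 ± 5.84) also rose. Lilr4b and Lilrb4a, like Pira2 and Lilra6, are close paralogs between which reads are hard to assign. Egr1, an immediate-early transcription factor, rose from 0.567 ± 0.201 to 8.67 ± 4.03 FPKM. Log2 fold changes of these genes were 3.27 (Wfdc17), 3.01 (Lsp1), 2.87 (Lilra6), 2.75 (Ccl3), 2.63 (Lilr4b), 2.57 (Serpina3g), 2.56 (Lilrb4a), 2.56 (Pira2) and 2.53 (Egr1). On the log2(FPKM + 1) scale used here, fold changes of genes near 1 FPKM are understated.

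Mpo fell from 1210 ± 152 to 345 ± 262 FPKM (log2 fold change -2.09, SE 0.35, limma adjusted p = 8.6e-04), and Ctsg, the granule protease cathepsin G, from 869 ± 131 to 437 ± 122 FPKM (-1.03, SE 0.18). Ms4a3, a membrane protein of granulocyte-monocyte progenitors, fell from 366 ± 61.9 to 160 ± 42.5 FPKM (-1.24). Adgrl4, an adhesion receptor (to 5.52 ± 1.9 FPKM, -1.09), Bace1, an aspartic protease (8.74 ± 1.8 to 3.91 ± 1.43, -1.03), and Ppic, a peptidyl-prolyl isomerase (32.2 ± 2 to 16.0 ± 3.12, -0.99), fell as well. Nebl, an actin-binding protein (-0.91), passed the same test. Mgl2, a macrophage lectin, fell from 37.1 ± 4.23 to 11.9 ± 5.99 FPKM (-1.81, adjusted p = 0.035), Cgnl1, a junction protein, by 0.89 log2 units (adjusted p = 0.011), and Vamp5, a vesicle fusion protein, by 0.77 (adjusted p = 0.010). The call of Mgl2 was lost without Renilla replicate 1 (adjusted p = 0.14), 2 (0.11) or 3 (0.087), or without e12.4 replicate 2 or 3 (0.053 each), and also without guide e12.4 (0.087), with pseudocount 0.1 (0.064), without a filter (0.08) or with only the groups of the comparison (0.064). The calls of Cgnl1 and Vamp5 were lost without Renilla replicate 1 (adjusted p = 0.081 and 0.11).

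On GRCm38/mm10, these genes lie as follows: Ctss (ENSMUSG00000038642.10, chromosome 3, 95526786-95556403, plus strand), Mpo (ENSMUSG00000009350.13, chromosome 11, 87793581-87804413, plus strand) and Ctsg (ENSMUSG00000040314.2, chromosome 14, 56099881-56102574, minus strand). Wfdc17 lies on chromosome 11 (83703991-83706268, plus strand), Lsp1 on chromosome 7 (142460809-142494867, plus strand), Ccl3 on chromosome 11 (83647844-83649355, minus strand), Egr1 on chromosome 18 (34859823-34864984, plus strand) and Ms4a3 on chromosome 19 (11629496-11640851, minus strand). Csf2rb lies on chromosome 15 (78325752-78353847, plus strand) and Cdkn1a on chromosome 17 (29090976-29100727, plus strand).

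Csf2rb, the common beta chain of the interleukin-3 receptor, rose from 46.5 ± 4.82 to 109 ± 20.6 FPKM (SE of the log2 fold change 0.14, limma adjusted p = 2.7e-05). Cdkn1a, the cell-cycle inhibitor p21, rose from 70.5 ± 5.81 to 132 ± 18.3 FPKM (0.89, adjusted p = 2.5e-05). Itgam rose from 50.9 ± 8.99 to 86.3 ± 19.5 FPKM (0.73, adjusted p = 0.026), a call lost without Renilla replicate 1 (0.58, adjusted p = 0.17) or 2 (0.77, adjusted p = 0.068). Hoxa9 and Meis1, homeobox targets of MLL fusions, were at 92.4 ± 10.9 against 90.6 ± 23.3 FPKM (0.06) and at 34.8 ± 2.2 against 35.3 ± 5.56 FPKM (-0.01), neither called. Myb and Myc, transcription factors of proliferating progenitors, were at 196 ± 36.9 against 232 ± 37.7 FPKM (-0.26) and at 107 ± 18.9 against 109 ± 5.96 FPKM (-0.04), neither called. Il3ra, the alpha chain of the interleukin-3 receptor (0.20), and Cd14, the endotoxin co-receptor (0.30), were not called either. Without e20.1 replicate 1, Cd14 was called (adjusted p = 0.041).

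**Figure D2:**
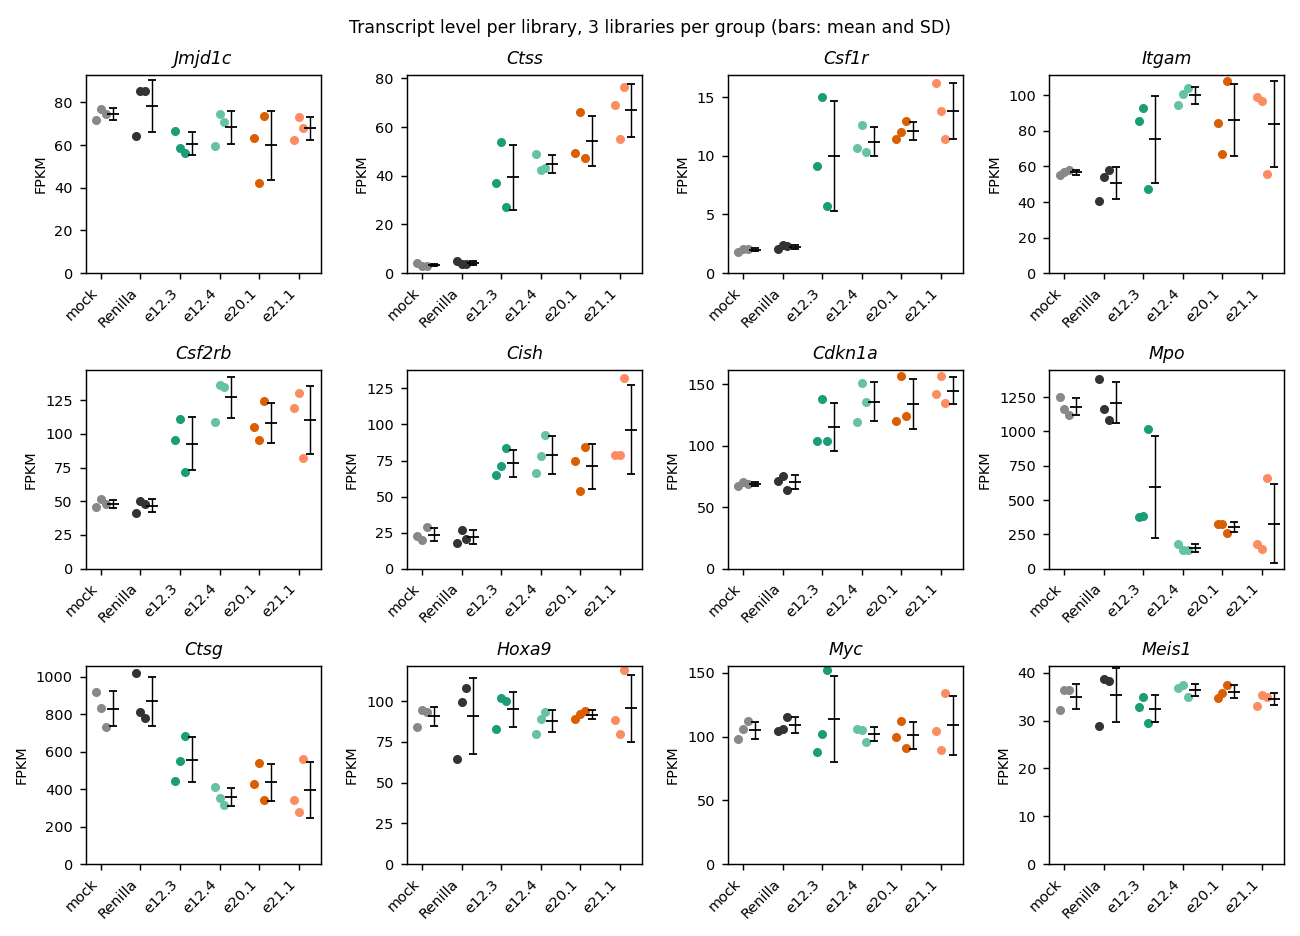
FPKM of 12 genes in the 18 libraries (1 dot each) with mean and SD per group of 3. Ctss, Csf1r, Csf2rb, Cish and Cdkn1a stand higher with each guide than in Renilla and mock, Mpo and Ctsg lower, with e12.3 replicate 3 (1020 FPKM) and e21.1 replicate 3 (664 FPKM) nearest to the controls for Mpo.

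In all, limma called 1268 of 11550 genes with the Jmjd1c guides against Renilla, 897 higher (70.7%) and 371 lower, and 217 and 13 of them changed by 2-fold or more. Of the called genes, 1140 had all 12 guide libraries on the called side of the Renilla mean. At an unadjusted p under 0.05 there were 2816 genes, against 578 expected by chance. The count was 815 (680 higher, 135 lower) without Renilla replicate 1 and 834 (639 higher, 195 lower) without Renilla replicate 2. In 91.7% of the called genes the change against mock had the same sign and an unadjusted limma p under 0.05, and 694 of the higher and 173 of the lower genes were also called against mock, with the same guide libraries in both comparisons.

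Monocyte genes rose with the guides: of 20 tested members of the monocyte and macrophage list 13 were called higher and 0 lower (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.92 (camera adjusted p = 7.71e-11). Csf1r, the receptor of macrophage colony-stimulating factor, rose from 2.25 ± 0.177 to 11.8 ± 2.76 FPKM, Tlr2, a receptor for bacterial lipopeptides, from 1.88 to 8.58 FPKM, and Irf8, a transcription factor of monocyte fate, to 43.3 ± 17.6 FPKM. The list stood lower by 0.89 and 0.41 in e12.3 replicate 3 and e21.1 replicate 3 than in the other libraries of their groups, and without them 14 members were called higher (median 1.01, adjusted p = 0.025 with an estimated correlation). Of 12 primary granule genes 0 were called higher and 5 lower (0 and 7 adjusted over the list alone), median -0.47, camera adjusted p = 2.2e-04, and adjusted p = 0.056 with an estimated correlation. Prtn3, the granule protease proteinase 3, fell from 1220 ± 34.7 to 832 ± 198 FPKM (-0.58), a call lost without Renilla replicate 1 (adjusted p = 0.1), 2 (0.081) or 3 (0.092). Primary granule genes stood 0.47 and 0.5 higher in the 2 libraries, and without them 8 were called lower (median -0.49, adjusted p = 0.068 with an estimated correlation).

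Mature neutrophil genes rose by a median of 0.74, 6 of 17 called higher and 1 lower (9 and 1 adjusted over the list alone), camera adjusted p = 1.25e-05, and adjusted p = 0.12 with an estimated correlation. Mmp8, the neutrophil collagenase, rose from 0.278 FPKM to 4.03 ± 1.35, Hp (haptoglobin) from 323 ± 53.9 to 592 ± 119 FPKM, and Padi4, a histone-modifying enzyme of neutrophils, from 2.34 to 10.2 ± 6.49 FPKM. This list stood 0.81 and 0.48 higher in e12.3 replicate 3 and e21.1 replicate 3, and without them 10 members were called higher and 2 lower (median 0.67, adjusted p = 0.22 with an estimated correlation). Markers of mast cells, basophils and eosinophils fell by a median of 0.52 with 0 of 8 called (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00701, and adjusted p = 0.15 with an estimated correlation). In the same 2 libraries that list stood at -0.45 and -0.67, and without them 3 members were called lower (median -0.38, camera adjusted p = 0.0108). Of the 14 stem and progenitor markers 1 was called higher and 2 lower (1 and 4 adjusted over the list alone; median -0.03, camera adjusted p = 0.353): Cd93, a lectin-like receptor, rose from 49.3 ± 2.12 to 91.7 ± 18.3 FPKM and Muc13, a mucin, fell from 14.9 to 8.91 FPKM. Stem and progenitor markers stood at -0.35 and -0.09 in the 2 libraries, and without them 2 were called higher and 4 lower (median -0.1, camera adjusted p = 0.348).

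Markers of other blood lineages were few. Of 4 dendritic cell markers tested 2 were called higher (4 adjusted over the list alone), among them Id2, a helix-loop-helix inhibitor, from 0.731 to 3.29 FPKM. Itgax, the integrin CD11c, lost its call without Renilla replicate 1, 2 or 3 (limma adjusted p = 0.12, 0.089 and 0.09). Itgb3, a platelet integrin, rose from 6.12 ± 0.673 to 22.3 ± 5.49 FPKM, while the other megakaryocyte marker Itga2b was not called (10.2 against 10.1 FPKM). Of the erythroid markers Gata1 and Tfr2 and of the lymphoid markers Cd3d and Lck, 0 were called by limma (1 erythroid marker lower adjusted over its list alone). Tfr2, the transferrin receptor 2, was called lower without e21.1 replicate 3 (-0.74, adjusted p = 0.029). Lck was called lower without e12.3 replicate 3 and e21.1 replicate 3 (-0.59, adjusted p = 0.013). Of 5 stromal and endothelial markers 1 was called higher, Pecam1, an adhesion molecule also of leukocytes (median 0.05, camera adjusted p = 0.14).

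Interleukin-3 and STAT5 targets rose, with 13 of 22 called higher and 0 lower (14 and 0 adjusted over the list alone), median 0.47, camera adjusted p = 7.71e-11. Cish, a feedback inhibitor of STAT5, rose from 21.8 ± 4.8 to 79.9 ± 19.2 FPKM (log2 fold change 1.82, limma adjusted p = 4.9e-06), and Osm, the cytokine oncostatin M, from 6.52 ± 0.519 to 19.4 ± 4.61 FPKM. Csf2rb2, a paralog of Csf2rb, rose from 4.93 to 17.5 ± 3.83 FPKM. Whether reads were assigned correctly between these paralogs was not tested, so their rises may not be separate. RAS-MAPK response genes rose by a median of 0.42, 7 of 16 called higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 1.98e-06, and adjusted p = 0.15 with an estimated correlation). Fos, an AP-1 subunit, rose from 2.01 ± 0.621 to 12.2 ± 7.42 FPKM, and Ier3, an early response gene, from 5.96 to 18.9 ± 5.88 FPKM. The RAS-MAPK list stood 0.6 and 0.62 higher in e12.3 replicate 3 and e21.1 replicate 3, and without them 7 members were called higher (median 0.33, adjusted p = 0.06 with an estimated correlation).

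Of 15 NF-kB and inflammatory genes 8 were called higher (10 adjusted over the list alone), median 0.65, camera adjusted p = 1.57e-08; Zfp36, an mRNA decay factor, rose from 12.5 to 29.1 ± 6.77 FPKM. Of 15 interferon response genes 6 were called higher (9 adjusted over the list alone), median 0.50, camera adjusted p = 3.39e-08, with Zbp1, a nucleic acid sensor, up from 0.239 to 2.86 ± 0.769 FPKM and Ifi27l2a from 2.11 to 9.69 ± 3.1 FPKM. Of 13 antigen presentation genes 9 were called higher (11 adjusted over the list alone), median 0.46, camera adjusted p = 1.4e-07, with H2-T23, a class Ib molecule, up from 30.9 ± 4.7 to 65.2 ± 15 FPKM. None of these lists held a member called lower. The antigen presentation list stood at -0.04 in e12.3 replicate 3 and 0.59 in e21.1 replicate 3, and without them 9 members were called higher (median 0.42, adjusted p = 0.058 with an estimated correlation).

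MLL-fusion target and leukaemia stem cell genes stood at a median of -0.02, 1 of 21 called higher (1 adjusted over the list alone) and 0 lower, camera adjusted p = 0.552. The member called was Bcl2, a survival factor (5.13 ± 0.329 to 8.23 ± 0.89 FPKM). Without Renilla replicate 1 the list was called lower at the preset correlation (camera adjusted p = 0.048). With an estimated correlation and all libraries its camera adjusted p was 0.77. Bmi1, a Polycomb protein, was called lower without e12.3 replicate 3 and e21.1 replicate 3 (-0.23, limma adjusted p = 0.022), and Lmo2, a transcriptional adaptor, without e12.3 replicate 2 (adjusted p = 0.033). In e12.3 replicate 3 and e21.1 replicate 3 the list stood at -0.24 and -0.13, and without them 1 member was called higher and 1 lower (median -0.02, camera adjusted p = 0.756). MYC target and ribosome biogenesis genes fell by a median of 0.32, 0 of 29 called higher and 8 lower (0 and 24 adjusted over the list alone; camera adjusted p = 3.03e-10, and adjusted p = 0.15 with an estimated correlation). Wdr12, a ribosome assembly factor, fell from 91.7 ± 8.95 to 65.5 ± 7.64 FPKM, and Wdr43, a factor of rRNA processing, from 59.6 to 46.6 FPKM. MYC targets stood at -0.04 and -0.33 in the 2 libraries, and without them 12 were called lower (median -0.30, adjusted p = 0.22 with an estimated correlation). The MYC list also stood 0.15 higher in Renilla than in mock, so the size of its fall depends on the control.

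Of 20 p53 targets 7 were called higher and 0 lower (8 and 0 adjusted over the list alone), median 0.30, camera adjusted p = 2.68e-06, with Trp53inp1, a p53-induced stress protein, up from 2.41 ± 0.793 to 7.33 ± 1.35 FPKM and Fas, a death receptor, from 3.93 to 8.70 FPKM. Of 23 BCL2-family and caspase genes 10 were called higher and 0 lower (11 and 0 adjusted over the list alone), median 0.30, camera adjusted p = 1.98e-06, with Mcl1, a survival factor, up from 66.1 to 89.3 ± 7.15 FPKM. This list holds genes that drive and genes that restrain cell death, and shares members such as Pmaip1 with the p53 list. Its member with the smallest limma p was Bmf, which drives cell death. S-phase and E2F target genes stood at a median of -0.02 with 0 of 29 called by limma (0 adjusted over the list alone; camera adjusted p = 0.748), and at -0.33 and -0.69 in e12.3 replicate 3 and e21.1 replicate 3. Without these libraries 3 S-phase genes were called higher and 1 lower (median 0.04, camera adjusted p = 0.272). G2/M genes fell by a median of 0.16, 1 of 25 called lower (0 adjusted over the list alone), camera adjusted p = 0.0046, and adjusted p = 0.45 with an estimated correlation. The G2/M member called was Cenpe, a kinetochore motor (24.9 to 19.6 FPKM), a call lost without Renilla replicate 1, 2 or 3 (adjusted p = 0.14, 0.07 and 0.11), and the list stood 0.33 and 0.47 higher in the 2 libraries. Without them 7 G2/M genes were called lower (median -0.25, adjusted p = 0.22 with an estimated correlation).

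Amino acid genes under ATF4 fell by a median of 0.31 with 0 of 26 called higher and 2 lower (0 and 3 adjusted over the list alone; camera adjusted p = 2.75e-05, and adjusted p = 0.39 with an estimated correlation). Shmt2, a mitochondrial serine enzyme, fell from 337 to 271 ± 20 FPKM. ATF4 genes stood 0.79 and 0.58 higher in e12.3 replicate 3 and e21.1 replicate 3, and without these libraries 22 members were called lower (median -0.40, adjusted p = 0.0082 with an estimated correlation). Atf4 itself was not called, but was without e12.3 replicate 3 (-0.32, adjusted p = 0.035) or e20.1 replicate 2 (adjusted p = 0.034). Cholesterol synthesis genes rose by a median of 0.23 with 3 of 25 called higher (3 adjusted over the list alone; camera adjusted p = 7.98e-04, and adjusted p = 0.45 with an estimated correlation), stood at -0.67 and -0.53 in these libraries, and without them 11 were called. Sc5d, a sterol desaturase, rose by 0.66, Fdft1, the squalene synthase, from 26.8 to 39.8 FPKM, and Mvd, a mevalonate decarboxylase, from 36.6 to 59.7 FPKM. Without Renilla replicate 2 the calls of Fdft1 (adjusted p = 0.067) and Mvd (0.093) were lost, as was that of Mvd without Renilla replicate 3 (0.054). Fatty acid synthesis genes stood at -0.02 with 0 of 16 called by limma (0 adjusted over the list alone; camera adjusted p = 0.917) and at -0.44 and -0.37 in the same libraries, without which 2 were called higher and 1 lower (median 0.15, camera adjusted p = 0.355).

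Glycolysis and hypoxia genes rose by a median of 0.11 with 6 of 27 called higher (7 adjusted over the list alone; camera adjusted p = 9.97e-04, and adjusted p = 0.45 with an estimated correlation), and stood 0.52 and 0.4 higher in e12.3 replicate 3 and e21.1 replicate 3. Without these libraries 7 were called higher and 1 lower (median 0.08, camera adjusted p = 0.0303). Slc2a3, the glucose transporter GLUT3, rose from 2.02 to 12.6 ± 9.61 FPKM. Oxidative phosphorylation genes fell by a median of 0.16 with 4 of 35 called lower (4 adjusted over the list alone; camera adjusted p = 3.64e-04, and adjusted p = 0.45 with an estimated correlation), and were not called without Renilla replicate 1 (camera adjusted p = 0.167). Mitochondrially encoded genes rose by a median of 0.58 with 2 of 13 called higher (7 adjusted over the list alone; camera adjusted p = 7.25e-05, and adjusted p = 0.23 with an estimated correlation), mt-Nd1 from 2420 ± 420 to 3460 ± 311 FPKM. Without Renilla replicate 1 the camera adjusted p of that list was 0.0622, and mt-Nd1 and mt-Nd2, subunits of complex I, lost their calls (adjusted p = 0.11 and 0.22). Against mock, mt-Nd1 (0.36, limma adjusted p = 0.095) and mt-Nd2 (0.37, adjusted p = 0.42) were not called, and the list stood 0.32 lower in Renilla than in mock. In e12.3 replicate 3 and e21.1 replicate 3 it stood at -0.27 and 0.28, and without them 3 members were called higher (median 0.58, adjusted p = 0.31 with an estimated correlation). Ribosomal protein genes stood at 0.05 with 0 of 33 called by limma (0 adjusted over the list alone; camera adjusted p = 0.552), and 0.34 and 0.44 higher in e12.3 replicate 3 and e21.1 replicate 3, without which their median was -0.02.

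H3K9 methylation regulators fell by a median of 0.15 with 1 of 20 called higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.28 with an estimated correlation). Suv39h2, an H3K9 methyltransferase, fell from 13.7 to 9.63 FPKM, and Kdm7a, a histone demethylase, rose from 2.12 to 4.97 FPKM. The H3K9 list stood 0.15 and 0.06 higher in e12.3 replicate 3 and e21.1 replicate 3. Without these libraries its member Ehmt1 was called lower (-0.3, limma adjusted p = 0.03). Of 25 lists tested, 19 were called with the preset correlation, 12 up and 7 down. With an estimated correlation 7 calls hold: monocyte and macrophage, interleukin-3 and STAT5, NF-kB, interferon, antigen presentation, BCL2-family and p53 lists.

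**Figure D3:**
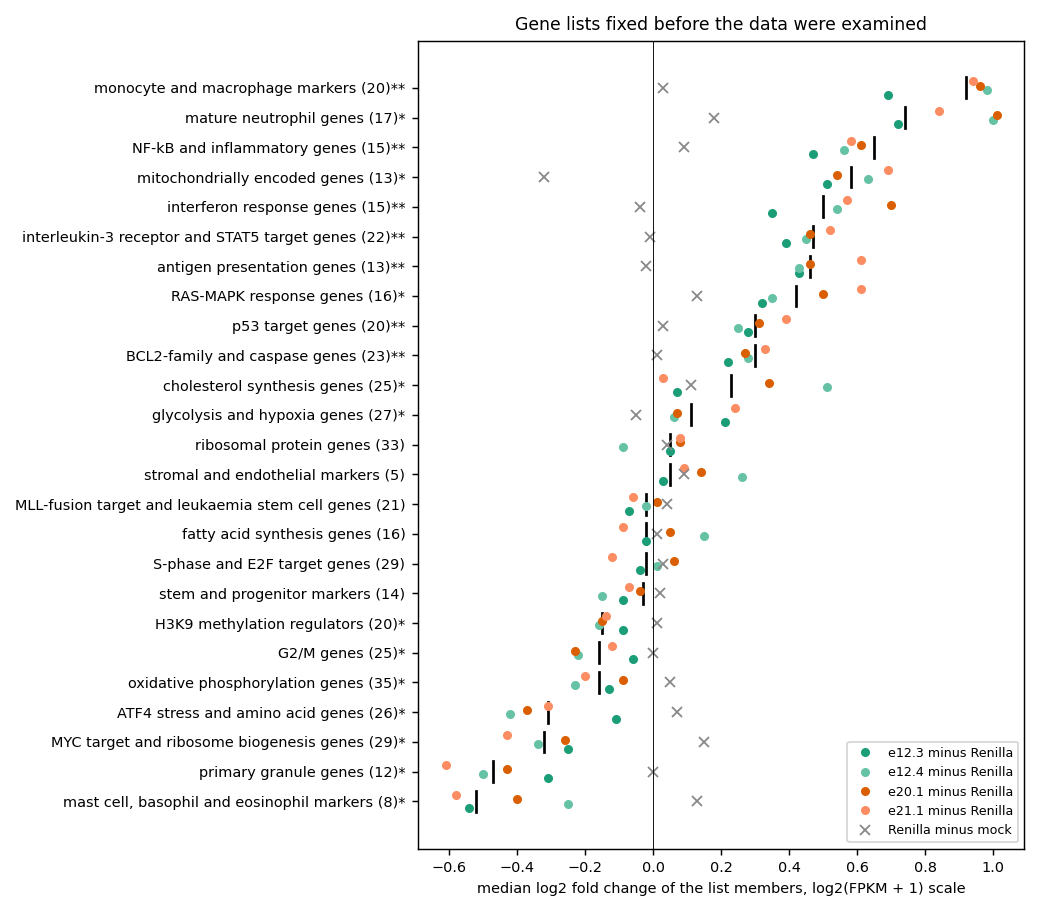
Median log2 fold change (log2(FPKM + 1) scale) of the tested members of 25 gene lists, number of members in brackets, for each guide against Renilla (dots), the 4 guides together (black tick) and Renilla minus mock (cross). A star marks lists called by camera for the 4 guides together and a double star those called also with an estimated correlation; monocyte and macrophage markers reach 0.92, and primary granule genes -0.47.

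With guide e12.3, Ctss rose to 39.3 ± 13.4 FPKM (n = 3; log2 fold change 2.96, limma adjusted p = 3.4e-06), Lsp1 to 37.6 ± 15, Wfdc17 to 195 ± 125, Lilra6 to 24 ± 10.4 and Ccl3 to 46.9 ± 17.1 FPKM. Usp11, a deubiquitinase, fell from 12.8 to 7.80 ± 0.451 FPKM, Fbxl19, a CpG-binding F-box protein, from 14.0 to 8.72 ± 1.15 FPKM, and Ppic to 19.1 ± 3.38 FPKM. Ctnnd1, a catenin, was lower by 0.67, a call lost without Renilla replicate 1 (adjusted p = 0.12) or 2 (0.078) or e12.3 replicate 3 (0.093). Ms4a3 was at 189 ± 42.2 FPKM (adjusted p = 0.043), and its call was lost without any 1 of the e12.3 and Renilla replicates 1 to 3 (adjusted p from 0.061 to 0.18). With only the e12.3 and Renilla libraries in the limma model, the calls of Usp11 (adjusted p = 0.17), Fbxl19 (0.11), Ppic (0.1), Wfdc17 (0.091), Ctnnd1 (0.21) and Ms4a3 (0.13) were lost. Against mock, those of Fbxl19 (adjusted p = 0.091) and Ctnnd1 (0.074) were lost. Mpo was at 595 ± 372 FPKM. In all 370 genes were called, 350 higher and 20 lower, with 1541 at an unadjusted p under 0.05 and 578 expected. The lower calls were 8, 11 and 8 without Renilla replicate 1, 2 and 3, and 13 without e12.3 replicate 2. Camera called 17 lists, 7 of them with an estimated correlation.

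With guide e12.4, Mpo fell to 151 ± 27 FPKM (log2 fold change -2.99, SE 0.44, limma adjusted p = 4.4e-04), Ms4a3 to 139 ± 6.55, Bace1 to 2.80 ± 0.586 and Adgrl4 to 4.30 ± 0.489 FPKM. Slc28a2, a nucleoside transporter, fell from 13.8 to 3.68 FPKM (adjusted p = 0.019), a call lost without any 1 of the e12.4 and Renilla replicates 1 to 3 (adjusted p from 0.05 to 0.08). Wfdc17 rose to 280 ± 10.3, Ctss to 44.8 ± 3.71, Lsp1 to 42.7 ± 5.13, Lilra6 to 34.9 ± 3.58 and Lilr4b to 78.8 ± 22 FPKM. In all 819 genes were called, 643 higher and 176 lower, with 2312 at an unadjusted p under 0.05. The count was 532, 495 and 497 without e12.4 replicate 1, 2 and 3, with 77, 56 and 66 lower. Without Renilla replicate 1 and 2 the lower calls were 59 and 101. Camera called 19 lists, 7 of them with an estimated correlation.

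With guide e20.1, Wfdc17 rose to 315 ± 89.2 FPKM (log2 fold change 3.56, limma adjusted p = 4e-05), Ctss to 54.2 ± 10.2, Lsp1 to 46.4 ± 6.88, Lilra6 to 34 ± 6.16 and Ccl3 to 74.8 ± 9.54 FPKM. Mpo fell to 304 ± 39.5 FPKM (-1.99, adjusted p = 0.013), a call lost without Renilla replicate 1 (adjusted p = 0.054) or e20.1 replicate 3 (0.057). Adgrl4 was lower by 1.03, a call lost without Renilla replicate 1, 2 or 3 (adjusted p = 0.1, 0.075 and 0.084) or e20.1 replicate 2 or 3 (0.14 and 0.057). Cgnl1 lost its call without Renilla replicate 1 (adjusted p = 0.077) or e20.1 replicate 2 (0.09), and Bace1 without Renilla replicate 3 (0.072) or e20.1 replicate 2 (0.07). The pseudogene Mid1-ps1 was called lower, but not without Renilla replicate 1, 2 or 3 (adjusted p = 0.082, 0.13 and 0.14) or e20.1 replicate 1 or 2 (0.069 and 0.19). In all 656 genes were called, 533 of them higher and the rest lower, with 2076 at an unadjusted p under 0.05. The count was 403 without Renilla replicate 2 and 436 without e20.1 replicate 3. The lower calls were 50, 42 and 61 without Renilla replicate 1, 2 and 3, and 54 and 72 without e20.1 replicate 2 and 3. Camera called 18 lists, 7 of them with an estimated correlation.

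With guide e21.1, Ctss rose to 66.8 ± 11 FPKM (log2 fold change 3.75, limma adjusted p = 9.9e-08), Wfdc17 to 294 ± 73.4, Lsp1 to 57.9 ± 12.7, Ccl3 to 86.0 ± 7.25 and Egr1 to 13.4 ± 3.84 FPKM. Ms4a3 fell to 120 ± 46.5 FPKM (-1.67), Ppic to 13.2 ± 3.03 (-1.25), Ctsg to 394 ± 149 (-1.19) and Mpo to 329 ± 290 FPKM (-2.21, adjusted p = 4.5e-03). Mgl2 was lower by 2.40, a call lost without Renilla replicate 1, 2 or 3 (adjusted p = 0.092, 0.079 and 0.066) or e21.1 replicate 3 (0.12). With only the e21.1 and Renilla libraries in the limma model, the calls of Mpo (adjusted p = 0.085), Ctsg (0.072) and Mgl2 (0.17) were lost. In all 1098 genes were called, 815 higher and 283 lower, with 2657 at an unadjusted p under 0.05. The lower calls were 140 and 167 without Renilla replicate 1 and 2, and 145 without e21.1 replicate 3. Camera called 16 lists, 8 of them with an estimated correlation.

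The monocyte and macrophage list stood at medians of 0.69, 0.98, 0.96 and 0.94 with e12.3, e12.4, e20.1 and e21.1, and the primary granule list at -0.31, -0.50, -0.43 and -0.61. Interleukin-3 and STAT5 targets stood at 0.39, 0.45, 0.46 and 0.52. With all 4 guides 316 genes were called higher and 13 lower, and with at least 1 guide 926 and 369. Across genes, the log2 fold changes of 2 guides correlated at Pearson 0.71 to 0.89 (Spearman 0.65 to 0.89), and genes are not independent replicates. The shared Renilla libraries alone give 0.51 in simulated unchanged groups. The highest Pearson value was that of e12.3 and e21.1, whose replicate 3 libraries stand apart together. Without those 2 libraries the Pearson range was 0.81 to 0.89, with 0.86 for e12.3 and e21.1. With all libraries, covariance was 0.0941 to 0.1399 against 0.0288 simulated. Between 2 guides, 320 to 545 higher calls were shared against 16.2 to 45.4 expected, 13 to 117 lower calls against 0.2 to 4.3, and 0 genes were called in opposite directions; simulated unchanged groups shared 0 calls. The expected numbers take the calls of 2 guides as independent, and the simulated groups have no calls to share, so neither measures what the shared Renilla libraries add. With 1 guide against Renilla and the other against mock, the correlation across genes was 0.52 to 0.71. These comparisons share no control library, so the simulated 0.51 is not a baseline for them, and none was simulated.

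Between the guide pairs that share the start of their names, Ctss stood at 39.3 and 44.8 FPKM with e12.3 and e12.4 and at 54.2 and 66.8 FPKM with e20.1 and e21.1 (log2 difference 0.52, limma adjusted p = 1). Egr1 stood at 4.78, 8.57, 7.94 and 13.4 FPKM (0.62), Ccl3 at 46.9, 67.5, 74.8 and 86.0 FPKM (0.53), and Xaf1, an interferon-induced apoptosis factor, at 1.64, 2.27, 2.88 and 3.31 FPKM (0.49). Mpo, Csf2rb and Hoxa9 differed by -0.01, 0.01 and 0.03. By limma 0 genes differed between the pairs, with 179 at an unadjusted p under 0.05 where 578 are expected by chance. With fewer such genes than chance gives, the p-values here run large, and 0 calls do not show that the pairs are alike. The median gene had a standard error of 0.109, so that a 95% interval spans 0.21 log2 units to either side. Without the 4 libraries that stand apart the median standard error was 0.081, and 332 genes had an unadjusted p under 0.05. Without e12.3 replicate 3, 1 gene was called, BX890553.1.

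In the camera test between the pairs, 13 of 25 gene lists were called with the preset correlation, 9 higher and 4 lower with e20.1 and e21.1. With an estimated correlation 3 hold, all higher: interferon response genes (median 0.13, adjusted p = 0.0073), p53 targets (0.1, adjusted p = 0.013) and interleukin-3 and STAT5 targets (0.07, adjusted p = 0.032). Without e12.3 replicate 3 and e21.1 replicate 3 only interferon response genes do (adjusted p = 0.046, against 0.077 for interleukin-3 and STAT5 targets and 0.055 for p53 targets). Between guides of the same pair (e12.4 against e12.3 and e21.1 against e20.1) the medians were of like size for interferon response genes (0.11 and 0.16) and p53 targets (0.08 and 0.09). For interleukin-3 and STAT5 targets they were 0.03 and 0.17, below and above the 0.07 between the pairs. The test takes libraries and not the 2 guides of a pair as replicates.

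**Figure D4:**
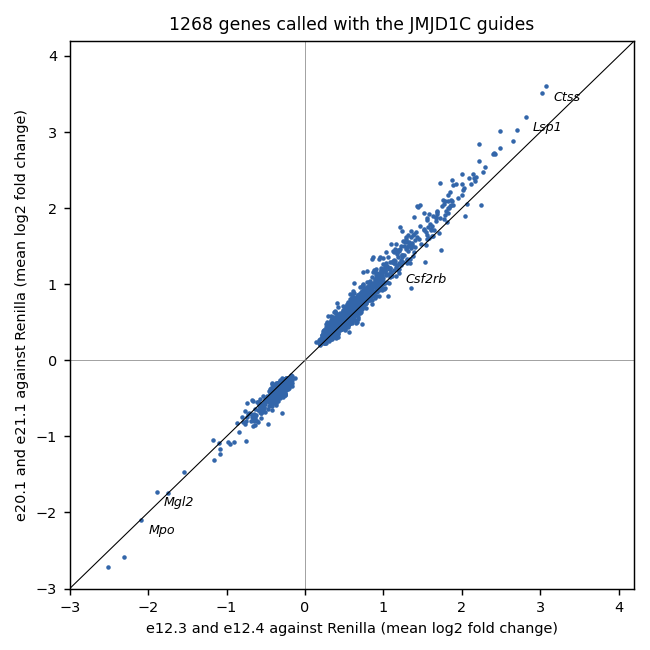
Each dot is 1 of the 1268 genes called with the Jmjd1c guides: mean log2 fold change against Renilla of e12.3 and e12.4 (x axis) and of e20.1 and e21.1 (y axis), with the line of equal change. All 1268 have the same sign in both pairs (values from -2.72 to 3.6), which is in part built in, since the genes were selected as called and both axes share the Renilla libraries.

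Within the pairs, Mpo was at 151 ± 27 FPKM with e12.4 and 595 ± 372 FPKM with e12.3 (log2 difference -1.82, SE 0.44, limma adjusted p = 0.9), with e12.3 replicate 3 at 1020 FPKM. Egr1 differed by 0.67 between e21.1 and e20.1 (limma adjusted p = 0.88). By limma 0 genes differed between e12.4 and e12.3 (414 at an unadjusted p under 0.05) and 0 between e21.1 and e20.1 (417). In each of these comparisons 578 are expected by chance. Without e12.3 replicate 3, BX890553.1 was called between e12.4 and e12.3. Without e12.3 replicate 3 and e21.1 replicate 3, Mpo (-1.34) and Mgl2 (-0.89) were called there too (limma adjusted p = 0.0031 for each), and Mpo was also called with array weights (adjusted p = 0.016). Cholesterol synthesis genes stood higher with e12.4 than e12.3 (median 0.38) and lower with e21.1 than e20.1 (-0.30), with e12.3 replicate 3 and e21.1 replicate 3 at -0.67 and -0.53 in their groups, and without these libraries the medians were 0.16 and -0.06. Of 14 and 10 lists called by camera 0 hold with an estimated correlation.

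Between Renilla and mock, Ctss was at 4.04 ± 0.808 and 3.35 ± 0.589 FPKM, Mpo at 1210 ± 152 and 1180 ± 63.9 FPKM and Wfdc17 at 25.3 ± 1.34 and 22.0 ± 2.44 FPKM, none called. By limma 0 genes differed, with 127 at an unadjusted p under 0.05 where 578 are expected by chance, so these p-values also run large. Without the 2 and the 4 libraries that stand apart the number was 265 and 489, still with 0 called. With all libraries, camera called 2 lists, mitochondrially encoded genes lower (median -0.32, adjusted p = 1.9e-05) and MYC targets higher (0.15, adjusted p = 1.76e-04). Each had adjusted p = 0.97 with an estimated correlation.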

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

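Of the tests here, the control share of e12.3 replicate 3 and e21.1 replicate 3 was chosen only after the result was seen, as were the fits without the libraries that stand apart.

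Monocyte, lipid and stress genes moved in the same way in e12.3 replicate 3 and e21.1 replicate 3: across genes the deviations of these libraries from their groups correlate at 0.76, and genes are not independent replicates. Control cells mixed in are argued against as the only cause. The control share solved from rising genes is 0.45 and 0.08 and from falling genes 0.73 and 0.32. The difference is at least 0.25 in both libraries (intervals over genes -0.38 to -0.17 and -0.34 to -0.14). Control cells mixed in together with another change were not tested and are not excluded. In e12.3 replicate 3 the intervals of the shares were 0.38 to 0.51 (rising) and 0.63 to 0.82 (falling). Read sampling at low depth is argued against, since the correlation is 0.74 among 5356 genes of at least 20 FPKM, where reads are many. Yet e12.3 replicate 3 and e21.1 replicate 3 were the deepest guide libraries (66.8 and 74.9 M reads, with the next at 43.5 M). Other differences between libraries that go with depth were not tested. GC content and transcript length explain 0.032 of the variance of the deviation. A different culture state or harvest of these libraries may remain, and the labels hold no day or batch to test it.

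p53 targets rose with the Jmjd1c guides, which direct Cas9 to cut at a target in the mouse genome, while the Renilla guide has no target there. The median log2 fold change of 10 core p53 targets was 0.36 (bootstrap interval 0.09 to 0.63), 4 of them called higher, with 0.08 for Renilla against mock, so that a response to DNA breaks could account for it. Myeloid genes on the list outside the core are argued against as the only source, since the core targets alone rose (camera p = 0.019 with an estimated correlation). Whether core targets themselves move with maturation was not tested, so maturation is not excluded as a source. Within the core, Trp53inp1 (1.3) and Cdkn1a (0.89) rose most, while Aen (0.01), Bax (0.09) and Sesn2 (-0.18) were not called. DNA breaks and loss of Jmjd1c cannot be told apart, since every cutting guide here is directed against Jmjd1c. Neither breaks nor loss of Jmjd1c was measured.

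For Jmjd1c guides against Renilla, the real split called 1362 genes in a model of 2 sides. In a draw of 100 splits of the 15 libraries (of 455 possible), 4 called as many, the real one included. This share is only just under 0.05. A draw of this size leaves the share over all possible splits uncertain, so chance is not excluded. The splits also took no account of the replicate number. The highest other split called 2625, with e12.3 replicate 3, e20.1 replicate 2 and e21.1 replicate 3 on one side, which points to a structure of the samples. For single guides the 10 splits are too few for a share under 0.05: e12.3 called 370 genes (highest other 0; 1 of 10), e12.4 819 (highest other 0; 1 of 10), e20.1 656 (highest other 1; 1 of 10) and e21.1 1098 (highest other 0; 1 of 10). For the pair difference the real count is 0, which each of the 100 splits must reach (100 of 100, highest other 5), so the splits say nothing about it. For e12.4 against e12.3, e21.1 against e20.1 and Renilla against mock the 10 splits are too few for a share under 0.05 (10 of 10 as large, real 0, highest other 0).

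Gene lists called between the guide pairs, where limma called 0 genes (179 at an unadjusted p under 0.05), numbered 13, against 14 between e12.4 and e12.3 and 10 between e21.1 and e20.1, which are guides of the same pair; fry called 1 between the pairs. Higher with e20.1 and e21.1 were monocyte and macrophage markers (median log2 difference 0.21), RAS-MAPK response (0.19), antigen presentation (0.17), NF-kB (0.15), interferon response (0.13), p53 targets (0.1), ribosomal protein (0.08), interleukin-3 and STAT5 (0.07) and BCL2-family genes (0.05). Lower were cholesterol synthesis (-0.09), fatty acid synthesis (-0.09), ATF4 (-0.08) and MYC target genes (-0.04). Only interferon, p53 and interleukin-3 lists were called with an estimated correlation (adjusted p = 0.0073, 0.013 and 0.032).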

How the results depend on the processing

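Array weights, scalings, mock as control, protein-coding genes only, separate controls, means per guide and the fits without libraries that stand apart are tests chosen only after the data were seen. The tests on counts written in the design (TMM against DESeq2 factors, filterByExpr, the DESeq2 Wald test, counts summed per guide, TMM CPM) were not run, since the files hold FPKM.

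Jmjd1c guides against Renilla called 1268 genes, and 2109 (1268 higher, 841 lower) with Renilla and mock as control. Array weights gave 4864 (2433 higher, 2431 lower), an even split against 70.7% higher with equal weights. The weight of Renilla replicate 2 was 6.35, against 0.22 and 1.38 for Renilla replicates 1 and 3. The control side of the weighted fits therefore rests mostly on Renilla replicate 2. Without e12.3 replicate 3 and e21.1 replicate 3 the count was 2082 (1266 and 816), and without 4 libraries 2209 (1395 and 814). Leaving out 1 library gave 815 (without Renilla replicate 1) to 1499, and 834 without Renilla replicate 2. Pseudocount 0.1 gave 1278, the stricter filter 1107, upper-quartile scaling 1251, mock as control 1040, protein-coding genes only 1285 and leaving out 1 guide 871 to 1460.

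With array weights e12.3, e12.4, e20.1 and e21.1 called 2027 (1271 higher, 756 lower), 3908 (2000 and 1908), 3393 (1870 and 1523) and 2641 (1559 and 1082) genes, a more even split than with equal weights; without the 2 libraries e12.3, e12.4, e20.1 and e21.1 called 706, 1541, 1290 and 1243; without the 4 libraries 977, 1836, 1196 and 1745. With only the groups of the comparison e12.3 called 85, e20.1 415 and e21.1 326, while e12.4 called 1134. Leaving out 1 library gave 252 to 393 (e12.3), 495 to 639 (e12.4; 532, 495 and 497 without its replicate 1, 2 and 3), 403 to 518 (e20.1; 403 without Renilla replicate 2, 436 without its replicate 3) and 785 to 1018 (e21.1).

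Mpo, Mgl2, Ms4a3, Igfbp4 and BX890553.1 were among the calls that appeared where the count was 0. The pair difference gave 1 gene with array weights (Scrn3), without the 2 or the 4 libraries (BX890553.1) and without a filter (Phyhip); leaving out 1 library gave 0 to 1. Between e12.4 and e12.3 array weights called 3 (BX890553.1, Igfbp4, Mpo), the 2 libraries left out 3 (BX890553.1, Mgl2, Mpo), the 4 left out 4 (with Ms4a3) and no filter 1; leaving out 1 library gave 0 to 1, with 1 without e12.3 replicate 3. Without a filter e21.1 against e20.1 and Renilla against mock gave 1 each, and 0 with any 1 library left out. Renilla against mock gave 6 with array weights and 4 with only its groups. Means per guide gave 0 between pairs.

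Jmjd1c changed by -0.29, and by -0.42 to -0.22 with 1 library left out. It was called with array weights (-0.34, limma adjusted p = 4.1e-04), where the control side rests mostly on Renilla replicate 2. It was also called without the 4 libraries (-0.35, adjusted p = 0.017). These include Renilla replicate 1, with the lowest Jmjd1c of the Renilla libraries, and e20.1 replicate 2, with the lowest of the guide libraries. Hoxa9 reversed from 0.06 to -0.18 with array weights (adjusted p = 0.029), where Meis1 (-0.13), Myb (-0.32) and Il3ra (0.20) were called too. Of 7308 values of named genes under alternatives, 7028 were the same, 122 stronger, 157 weaker and 1 reversed.

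Named genes with the 4 guides also lost calls by limma without a filter (Mgl2, Itgam, Prtn3, Cenpe, Itgax, mt-Nd1 and mt-Nd2; adjusted p from 0.05 to 0.08) and with only the groups of the comparison (Mgl2, Prtn3, Cenpe and Itgax; 0.051 to 0.064). So did Itgam (0.1), Vamp5 (0.073) and Cenpe (0.063) against mock, and Itgam (0.1), Prtn3 (0.12), Cenpe (0.059), Fdft1 (0.05), Mvd (0.062) and mt-Nd2 (0.071) without guide e12.4. With e20.1, Adgrl4 was lost without a filter (0.072) and with only its groups (0.11).

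Gene lists called fell from 19 to 7 with an estimated correlation and to 15 with fry, and were 18 to 19 with 1 library left out. Agreement between guides had a median of 0.815 and of 0.66 with separate controls.

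The labels do not say that replicate numbers pair the libraries, and not every pair with the same number deviates together: the mean correlation across genes of 45 pairs with the same number was 0.13 (-0.25 to 0.76, 26 over 0.1), and -0.06 for pairs with different numbers. Deviations within a group cancel out by construction, so the second mean follows from the first and is no separate evidence. As a hint from the data, the best partner in another group had the same number for 17 of 18 libraries. With the number as a block, 1809 genes were called for the 4 guides, 550, 1196, 989 and 1652 for e12.3, e12.4, e20.1 and e21.1, and 0 in the other comparisons; Cd14 was called (limma adjusted p = 0.019), as were Lmo2 (0.029), Kif20a (0.035), Hsd17b7 (0.037), Slc7a1 (0.039) and Hdc (0.041), and Mid1-ps1 was not called with e20.1 (0.056). Lower calls with the block were 671 for the 4 guides and 64, 362, 292 and 583 for e12.3, e12.4, e20.1 and e21.1.

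Why these counts move was not tested: the cause was not tested for any of them. Depth limits genes near 1 FPKM, where a library of 20.7 M reads holds about 41 reads for a 2 kb transcript.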

Other observations

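Of the tests here, the share of called genes with the same sign against mock and the fits without libraries that stand apart were chosen only after the result was seen.

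Cish, Csf2rb, its paralog Csf2rb2 and Osm rose while the interleukin-3 receptor chain Il3ra was not called (55.7 ± 10.5 against 48.1 ± 7.49 FPKM). Monocyte genes (Ctss, Csf1r) rose, Mpo and Ctsg fell, and Mmp8 and Hp rose. The camera calls of the primary granule and mature neutrophil lists are lost with an estimated correlation (adjusted p = 0.056 and 0.12). Hoxa9, Meis1 and Myc were not called in the same libraries. Whether these genes changed in the same cells is not resolved by bulk RNA.

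Ctss rose with each guide, from 39.3 ± 13.4 FPKM with e12.3 to 66.8 ± 11 FPKM with e21.1. A single response of different size in each guide is a hypothesis: without e12.3 replicate 3 and e21.1 replicate 3, slopes of each guide on the mean of the others were 0.85, 1.04, 0.96 and 1.13 for e12.3, e12.4, e20.1 and e21.1, and the ratio of the largest to the smallest was 1.32 (bootstrap 1.3 to 1.35, 2073 genes). The difference between the guide pairs correlates with the common response at 0.49 across genes, which are not independent replicates, so a difference of size and one of kind cannot be told apart. Editing efficiency of each guide may differ, which these data do not measure.

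ATF4 and cholesterol genes depended on the libraries that stand apart: without e12.3 replicate 3 and e21.1 replicate 3, 22 ATF4 genes were called lower and 11 cholesterol genes higher.

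Of the 1268 genes called against Renilla, 91.7% have the same sign and an unadjusted limma p under 0.05 against mock, but at the adjusted threshold 694 of 897 higher and 173 of 371 lower genes are called there too, and both comparisons share the 12 guide libraries. GC content and transcript length explain 5.5e-04 of the variance of the log2 fold change across genes, which argues against a bias by gene composition.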
